A study of Homo sapiens with 12 samples.

How the data were processed

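Total RNA of JEG-3 cells was extracted with a column kit and made into libraries with a kit that does not mark strand, per the labels' protocols. The authors deposited 2 tables of a signal per gene symbol, named as normalised counts, with 29321 gene symbols and 1 row without a name each. Salmon 1.5.2, DESeq2, FastQC and the build GRCh38 are named in the submitters' processing notes, with no role or order, and the column names of the tables name Salmon. The gene annotation and any filter are not given in the sources used here. Every value was within 0.001 of a whole multiple of 1 step per library, for 100% of values, so the deposited values are whole reads per gene divided by 1 size factor per library, set within each table. Reads were recovered by dividing by that step. For 3 columns of the NLRP7 table, the step was close to 1.

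The recovered reads per library came to between 25540300 and 32158600 in the ELF3 table and between 31946500 and 35501200 in the NLRP7 table. The unnamed row held between 0.523% and 1.86% of reads in the ELF3 table and between 0.426% and 0.517% in the NLRP7 table, and stayed out of all totals and tests. Genes were placed with the GENCODE 29 annotation of GRCh38, in which 27682 of the symbols (94.4%) had a position. Groups were taken from the sample titles. The labels number 6 WT samples, while the columns of both tables number theirs 1 to 3, so WT columns were used as members of the WT group without a sample of their own. Within each group the reads of every pair of libraries differed by at least 4.51 times the sampling variance, so no library was counted as a duplicate.

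For each table, genes with a mean of at least 10 normalised read counts were tested with limma 3.58.1 (R 4.3.3) on log2(value + 1), with a variance trend and no covariate, and a Benjamini-Hochberg adjusted p under 0.05 counted as changed. Fold changes are on this scale, which understates those of low genes. Adjusted p-values without another name come from this test. The 2 tables were normalised separately, so every fold change was taken within its table. The difference between the knockouts was tested by limma on both tables joined, as the contrast of the 2 fold changes. Overlap was tested with Fisher's exact test, two-sided, and 5 overlaps were adjusted together. Single genes also had an exact two-sided permutation test. Before the data were examined, 29 gene lists were fixed, covering antigen presentation, interferon response, trophoblast cell types, stress, metabolism and markers of other cell types. Lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The 20 tested genes nearest to each targeted gene were summarised by their median with an order-statistic 95% interval, a step added after values near ELF3 were seen. The fry test, which asks whether a list's genes move one way on balance, was an alternative.

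The genes named were set by a rule fixed at the same time. It took ELF3, NLRP7, 5 HLA genes and B2M always, and the 10 largest rises and falls among changed genes with a mean of at least 50, no overlap between groups and an approved symbol of a gene that is not a pseudogene, antisense or read-through gene. It also took up to 4 members with the smallest p from each list with at least 3 changed members, and the 5 genes per direction with the largest smaller change in both knockouts. Other genes named in the report are members of a fixed list, chosen after their values were seen. XIST and Y-linked genes were left out.

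Alternatives covered the pseudocount, the filter, the scaling of libraries, the variance model, sample weights, replicate numbers as a block, each library left out in turn, stricter thresholds, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Reads were simulated from the means, library sizes and dispersions of each table, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean of at least 50, so recovery of lower genes was not measured. No shift shared by libraries of both groups was simulated, so the recovery need not hold where one is present. In the ELF3 comparison the test recovered 60% and 96% of the changed genes, with 6.02% of calls false among 13537 genes. In the NLRP7 comparison it recovered 85% and 100%, with 7.04% of calls false among 13651 genes. The median residual SD of log2 values was 0.239 in the ELF3 table and 0.123 in the NLRP7 table.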

Results

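RNA sequencing was performed on JEG-3 cells, a human choriocarcinoma line used as a model of placental trophoblast, and on JEG-3 lines in which ELF3 or NLRP7 had been knocked out. ELF3 is an epithelial transcription factor of the ETS family, and NLRP7 is an NLR-family protein whose maternal mutations are known in recurrent hydatidiform mole. The stated purpose was to learn how each gene bears on expression of HLA-C, the classical MHC class I molecule that trophoblast presents to maternal killer cells. The 12 libraries comprised 6 WT, 3 ELF3 knockout and 3 NLRP7 knockout libraries. They were deposited as 2 tables of normalised read counts, each holding 3 knockout and 3 WT libraries, with different WT libraries in each. The ELF3 table held between 25540300 and 32158600 recovered reads per library, and the NLRP7 table between 31946500 and 35501200. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries. Nor do they say whether a knockout was a pool of cells or a single clone, so an effect of the targeted gene cannot be told from a difference between clones. Each knockout was compared with the WT libraries of its own table.

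The ELF3 comparison asked how loss of ELF3 altered HLA-C and the remaining transcriptome. In the ELF3 knockout, the ELF3 transcript (chromosome 1, 202007945 to 202017188, GRCh38) stood at 1981, 1963 and 1327 normalised read counts in the individual libraries, against 4937, 5136 and 3089 in WT. Its log2 fold change was -1.31 (SE 0.229, adjusted p = 0.0238). The genes around ELF3 were examined after values near it were seen. The 20 tested genes nearest to it had a median log2 fold change of -0.58 (95% interval -0.77 to -0.07), a value that 0.512% of such windows reached, and RNPEP (-0.69), TIMM17A (-0.67), IPO9 (-0.59), UBE2T (-0.76) and KDM5B (-0.77) among them fell. Copy number was not measured, so whether the fall of ELF3 is in part a change of that segment stays open. HLA-C (chromosome 6, 31268749 to 31272130) fell from 12359 ± 2996 to 6797 ± 304 normalised read counts (SD, n = 3), a log2 fold change of -0.83 (SE 0.178, adjusted p = 0.0419). All 3 knockout libraries lay below all 3 WT libraries. The exact two-sided permutation test of HLA-C alone gave p = 0.1, the smallest value that 3 against 3 libraries allow. NLRP7 (chromosome 19, 54923509 to 54966312) fell in the ELF3 knockout as well, from 10431 ± 960 to 2243 ± 82.7 (SD, n = 3), with a log2 fold change of -2.21 (SE 0.107, adjusted p = 0.000117). The annotated NLRP7 gene overlaps NLRP2 on the opposite strand, and the library kit did not mark strand, so reads of the shared part cannot be told apart. NLRP2 did not fall with NLRP7. It stood at 93040, 91971 and 139721 normalised read counts in the ELF3 knockout libraries, against 69624, 76157 and 91783 in WT.

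Of the other MHC class I molecules, none passed the test in the ELF3 knockout. HLA-G, the nonclassical molecule of extravillous trophoblast, had a log2 fold change of -0.53 (SE 0.234, adjusted p = 0.260), and HLA-E had -0.26 (SE 0.209, adjusted p = 0.542). HLA-A and HLA-B stood at 103 ± 10.4 and 84.2 ± 13.7 normalised read counts (SD, n = 3) in the knockout, with log2 fold changes of 0.53 and 0.05. Reads can be shared among these near-identical genes, so their levels are uncertain. The light chain B2M, at 5528 ± 2630 against 4386 ± 604 (SD, n = 3), had a log2 fold change of 0.24 (SE 0.279, adjusted p = 0.692). The HLA-C call rested on small margins: it was lost when ELF3 knockout replicate 1, 2 or 3 or WT replicate 1 or 2 was left out (adjusted p = 0.114, 0.138, 0.0801, 0.128 and 0.158), and its adjusted p was 0.00858 without WT replicate 3 and 0.00230 with sample weights, with a log2 fold change between -1.05 and -0.70 with any library left out. Without the number 3 library of both groups, left out after the data were seen, HLA-C had a log2 fold change of -1.01 (adjusted p = 0.00637). The ELF3 call was likewise lost without ELF3 knockout replicate 1 or 2 or WT replicate 1 or 2 (adjusted p = 0.0553, 0.0619, 0.0981 and 0.104). With all libraries but no variance trend, the calls of HLA-C and ELF3 were lost too (adjusted p = 0.112 and 0.0764).

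**Figure D1:**
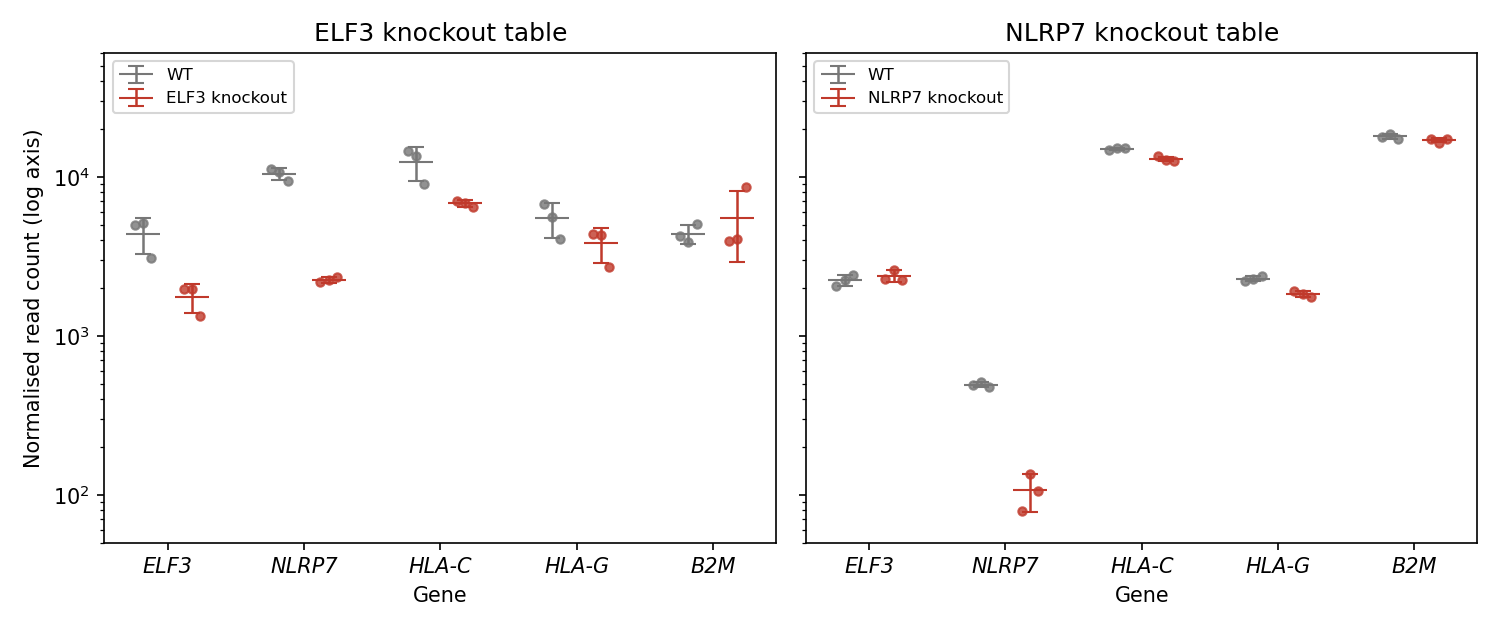
Normalised read count on a log axis of ELF3, NLRP7, HLA-C, HLA-G and B2M in the ELF3 knockout table (left) and the NLRP7 knockout table (right), with 1 point per library, horizontal bars at the mean and error bars of 1 SD over 3 libraries; WT is grey and the knockout red. HLA-C averaged 6797 in the ELF3 knockout against 12359 in its WT, and 12935 in the NLRP7 knockout against 15012 in its WT.

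Among the interferon-stimulated genes, 4 of 30 tested members fell in the ELF3 knockout and none rose (5 fell adjusted over the list alone). They were IFITM1, IFITM3 and IFITM2, membrane proteins that restrict viral entry, and IFIT1, an RNA-binding antiviral protein. IFITM2 (307631 to 315272), IFITM1 (313506 to 315272) and IFITM3 (319669 to 327537) are neighbours on chromosome 11. The annotated spans of IFITM1 and IFITM2 overlap, so reads may be shared between them. The IFITM genes are thus not independent members of the list. IFITM1 dropped from 358 ± 118 to 48.4 ± 9.45 and IFITM3 from 960 ± 251 to 315 ± 24.8 (SD, n = 3). The list as a whole lay lower (camera adjusted p = 0.0276; adjusted p = 0.703 with an estimated correlation). So did the 12 genes of MHC class I antigen processing (camera adjusted p = 0.0276; adjusted p = 0.703 with an estimated correlation), of which no single member passed over all genes and 1 fell adjusted over the list alone. Extravillous trophoblast markers lay higher as a list (camera adjusted p = 0.0130; adjusted p = 0.703 with an estimated correlation). In it 3 of 24 rose: the protease inhibitor SERPINE2 (log2 fold change 2.30, SE 0.221), the matrix protease MMP11 (2.48, SE 0.412) and ADAM19 (0.59, SE 0.111). The list counts 6 risen members adjusted over the list alone. Mesenchymal genes lay higher as a list (camera adjusted p = 0.0271; adjusted p = 0.703 with an estimated correlation), although the only member that passed over all genes, TWIST1, fell. Adjusted over the list alone, 4 of its 20 members rose (SPARC, COL1A1, LOX and TGFBI) and 1 fell. Histone genes lay lower with none of 16 passing (camera adjusted p = 0.0222, and adjusted p = 0.783 with an estimated correlation). They also differed by replicate number: the median log2 difference of number 3 from numbers 1 and 2 was -0.98 in WT and -0.59 in the knockout. Ribosomal protein genes lay lower with 3 of 60 members fallen, RPL34, RPL12 and RPSA (camera adjusted p = 0.0276, and adjusted p = 0.829 with an estimated correlation). The median of that list was only -0.09. It turned positive without WT replicate 1 (0.0228), without ELF3 knockout replicate 3 (0.00942) and with sample weights (0.000512). None of these 6 list calls thus held with an estimated correlation, and single libraries mattered as well: camera lost the extravillous list without WT replicate 3 (adjusted p = 0.0968), histones without ELF3 knockout replicate 3 or WT replicate 2 (0.138 and 0.289), ribosomal proteins without ELF3 knockout replicate 3 or WT replicate 1 (0.642 and 0.728), mesenchymal genes without ELF3 knockout replicate 1 or WT replicate 1 or 3 (0.0820, 0.120 and 0.0834), antigen processing without ELF3 knockout replicate 1 or 2 or WT replicate 1 or 3 (0.0828, 0.106, 0.099993 and 0.0834), and interferon-stimulated genes without ELF3 knockout replicate 2 or WT replicate 1, 2 or 3 (0.106, 0.0514, 0.0587 and 0.0834).

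Of 28 imprinted genes, 2 fell and 1 rose in the ELF3 knockout, without a shift of the list (camera adjusted p = 0.956). IGF2, a fetal growth factor, fell with a log2 fold change of -1.98 (SE 0.132), PEG10, needed for placental development, fell with a log2 fold change of -1.16 (SE 0.252), and GRB10 rose by 0.58 (SE 0.119). Of 22 immediate early genes, FOS (-0.68, SE 0.150) and EGR1 (-1.25, SE 0.231) fell and DUSP4 rose (0.84, SE 0.109). The list's median and mean were 0.01 and 0.05, while camera gave a downward direction (adjusted p = 0.860). Syncytiotrophoblast markers showed no shift of the list (camera adjusted p = 0.525): the aromatase gene CYP19A1 rose (0.90, SE 0.161) and XAGE3 fell (-2.03, SE 0.320), with 28 of 30 not passing, and these members, like CGA and the mesenchymal genes named above, were chosen after their values were seen. The number 3 libraries of both groups stood apart for this list: CGA, the common subunit of the glycoprotein hormones, was at 7418 normalised read counts in ELF3 knockout replicate 3 against 19522 and 19428 in replicates 1 and 2, and at 4660 in WT replicate 3 against 13467 and 13698. For each replicate number CGA thus stood higher in the knockout than in WT. CGB3, also chosen after its values were seen, did so too (1243, 1116 and 221 against 461, 480 and 106). Neither gene passed the test, whose spread includes the shift of the number 3 libraries. No other list of this table passed camera, the lowest being p53 targets (adjusted p = 0.0572), and the markers of leukocytes and endothelium had too few tested members for the test.

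The 10 largest falls in the ELF3 knockout left knockout means between 2.03 and 32.0 normalised read counts, the highest being that of KLK6. SYT5, a synaptotagmin, fell from 761 ± 169 to 2.03 ± 0.997 (SD, n = 3), and its chromosomal neighbour TNNI3, cardiac troponin I, from 146 ± 33.0 to 2.04 ± 1.77. SPATC1L (-5.66), the testis bromodomain gene BRDT (-5.42), the GABA transporter SLC6A11 (-4.60), FAM9C (-4.52), DUSP23 (-4.48), BOLA1 (-4.14), KIFBP (-4.08) and the kallikrein KLK6 (-3.97) followed, all as log2 fold changes of value plus 1. The largest rises were ARL14EP, from 10.4 ± 11.3 to 221 ± 46.3 (SD, n = 3; log2 fold change 4.85), AP3B2, from 12.8 ± 10.7 to 129 ± 92.4, RNF128, reaching 164 ± 56.1, the scavenger receptor STAB2 (3.26), the alkaline phosphatase ALPL (2.80), the BMP antagonist GREM1 (2.75), CCDC141 (2.70), TMPRSS3 (2.61), PPM1L (2.61) and MMP11 (2.48).

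In all, limma called 541 of 13676 tested genes changed in the ELF3 knockout, 232 higher and 309 lower. Of these, 110 rose and 187 fell at least 2-fold. The groups did not overlap for 26.2% of all tested genes, where chance gives 10%. The count depended on single libraries: it was 125, 120 and 503 without ELF3 knockout replicate 1, 2 or 3, and 143, 110 and 503 without WT replicate 1, 2 or 3, where 2 libraries remained in that group. It was 1099 with the number 3 library of both groups left out, an alternative chosen after seeing the data. Of 52 named genes past the threshold here or in the overlap, 24 stayed past it whichever library was left out, among them NLRP7, IGF2, IFITM1, SERPINE2, SYT5 and BRDT.

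The NLRP7 comparison asked the same of NLRP7 loss. The NLRP7 transcript stood at 78.5, 136 and 105 normalised read counts in the knockout libraries and at 487, 510 and 474 in WT, a log2 fold change of -2.23 (SE 0.192, adjusted p = 8.87e-05). HLA-C fell from 15012 ± 235 to 12935 ± 436 normalised read counts (SD, n = 3), with a log2 fold change of -0.22 (SE 0.0339, adjusted p = 0.00238) and all 3 knockout libraries below all WT libraries. The exact two-sided permutation test of HLA-C alone again gave p = 0.1, the smallest possible. HLA-G fell with it (-0.31, SE 0.0544, adjusted p = 0.00415). HLA-E (-0.10, SE 0.0488), HLA-A (-0.10, SE 0.120), HLA-B (-0.23, SE 0.170) and B2M (-0.08, SE 0.0374) did not pass (adjusted p = 0.184, 0.605, 0.388 and 0.182), nor did ELF3 (0.09, SE 0.0783, adjusted p = 0.479). Over the 7 class I molecules camera gave no shift (adjusted p = 0.121), with a median of -0.10 and a mean of 0.05. The fry test, which does not compare a list with other genes, passed for them (fry adjusted p = 0.00310), for antigen processing (0.00103) and for MHC gene regulators (0.0487). The 20 tested genes nearest to NLRP7 had a median log2 fold change of -0.00764 (95% interval -0.22 to 0.27). Among them 3 rose, including SYT5 (3.76), and 2 fell.

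In MHC class I antigen processing, 4 of 14 members fell and 1 rose in the NLRP7 knockout. TAPBP, the tapasin gene (-0.38, SE 0.0556), the peptide transporter TAP1 (-0.21, SE 0.0459) and the aminopeptidase ERAP1 (-0.31, SE 0.0685) were lower, and the chaperone CALR was higher (0.49, SE 0.138); the list did not pass camera (adjusted p = 0.118). Of 18 MHC gene regulators, 2 fell, IRF1 (-0.58, SE 0.0856) and STAT1 (-0.26, SE 0.0398), and 1 rose, RFX5 (0.61, SE 0.188). Of all tested genes, 20.8% were called, so these calls do not set the list apart. Adjusted over the list alone RFX5 did not pass. The list again showed no shift (camera adjusted p = 0.771). Interferon-stimulated genes lay lower as a list (camera adjusted p = 0.0178; adjusted p = 0.140 with an estimated correlation). In it 7 of 35 fell and none rose, including IFITM3 (-0.78, SE 0.0869) and the nuclear body protein SP100 (from 407 ± 44.1 to 203 ± 20.6; SD, n = 3).

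In the NLRP7 knockout, 21 of 33 syncytiotrophoblast markers fell and none rose (22 fell adjusted over the list alone). The list lay lower (camera adjusted p = 2.89e-11, and adjusted p = 0.0751 with an estimated correlation). CGA fell from 11939 ± 335 to 7164 ± 91.1 and the placental growth factor PGF from 37544 ± 821 to 25056 ± 99.9 normalised read counts (SD, n = 3). The T-box factor TBX3 (-0.52, SE 0.0403) and XAGE3 (-1.68, SE 0.125) were lower too. Of 21 cytotrophoblast markers 13 fell and 1 rose (15 and 1 adjusted over the list alone). That list lay lower too (camera adjusted p = 8.71e-09, and adjusted p = 0.0751 with an estimated correlation). TP63, a marker of trophoblast progenitors, dropped from 284 ± 10.7 to 52.2 ± 8.50, the laminin receptor subunit ITGA6 from 21006 ± 260 to 12614 ± 463 and EGFR from 7748 ± 64.2 to 4616 ± 193 (SD, n = 3), and the transcription factor GATA3 had a log2 fold change of -0.53 (SE 0.0305). Extravillous markers went both ways, 9 of 24 lower and 3 higher (camera adjusted p = 0.0805): the fibronectin receptor subunit ITGA5 (0.71, SE 0.0292) and the activin-binding FSTL3 (1.25, SE 0.0696) rose, while ADAM19 (-0.44, SE 0.0362) and fibronectin FN1 (-0.54, SE 0.0493) fell.

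In the integrated stress and unfolded protein response list 17 of 27 fell and 1 rose in the NLRP7 knockout (camera adjusted p = 8.71e-09; adjusted p = 0.0751 with an estimated correlation). The cystine transporter SLC7A11 fell from 1197 ± 37.8 to 514 ± 17.5, asparagine synthetase ASNS from 1921 ± 75.9 to 991 ± 105 and the serine synthesis enzyme PSAT1 from 7922 ± 166 to 5449 ± 175 (SD, n = 3). Of 23 immediate early genes 12 fell and none rose (camera adjusted p = 7.01e-05; adjusted p = 0.0751 with an estimated correlation), led by the nuclear receptor NR4A1 (-1.39, SE 0.0705) and the phosphatase DUSP5 (-0.84, SE 0.0541). Cell cycle genes lay higher as a list, 10 of 37 up and 4 down (camera adjusted p = 0.0165; adjusted p = 0.140 with an estimated correlation). The mitotic genes KIF20A (0.44, SE 0.0313) and CCNB1 (0.26, SE 0.0351) rose, whereas CCNE1 (-0.23, SE 0.0303) and CDC6 (-0.26, SE 0.0363), which act at entry into S phase, fell. In the hypoxia and glycolysis list 9 of 29 rose and 5 fell (camera adjusted p = 0.0182; adjusted p = 0.140 with an estimated correlation). Lactate dehydrogenase LDHA (0.73, SE 0.0364) was among the former and VEGFA (-0.39, SE 0.0483) among the latter. Mitochondrial transcripts lay higher (camera adjusted p = 0.0128; adjusted p = 0.793 with an estimated correlation), with MT-ND5 among 4 of 13 that rose and MT-ND3 fallen. The latter lists leaned on single libraries: the mitochondrial call was lost without NLRP7 knockout replicate 2 or WT replicate 2 (camera adjusted p = 0.0596 and 0.0548) and the hypoxia call without WT replicate 2 (camera adjusted p = 0.0548).

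**Figure D2:**
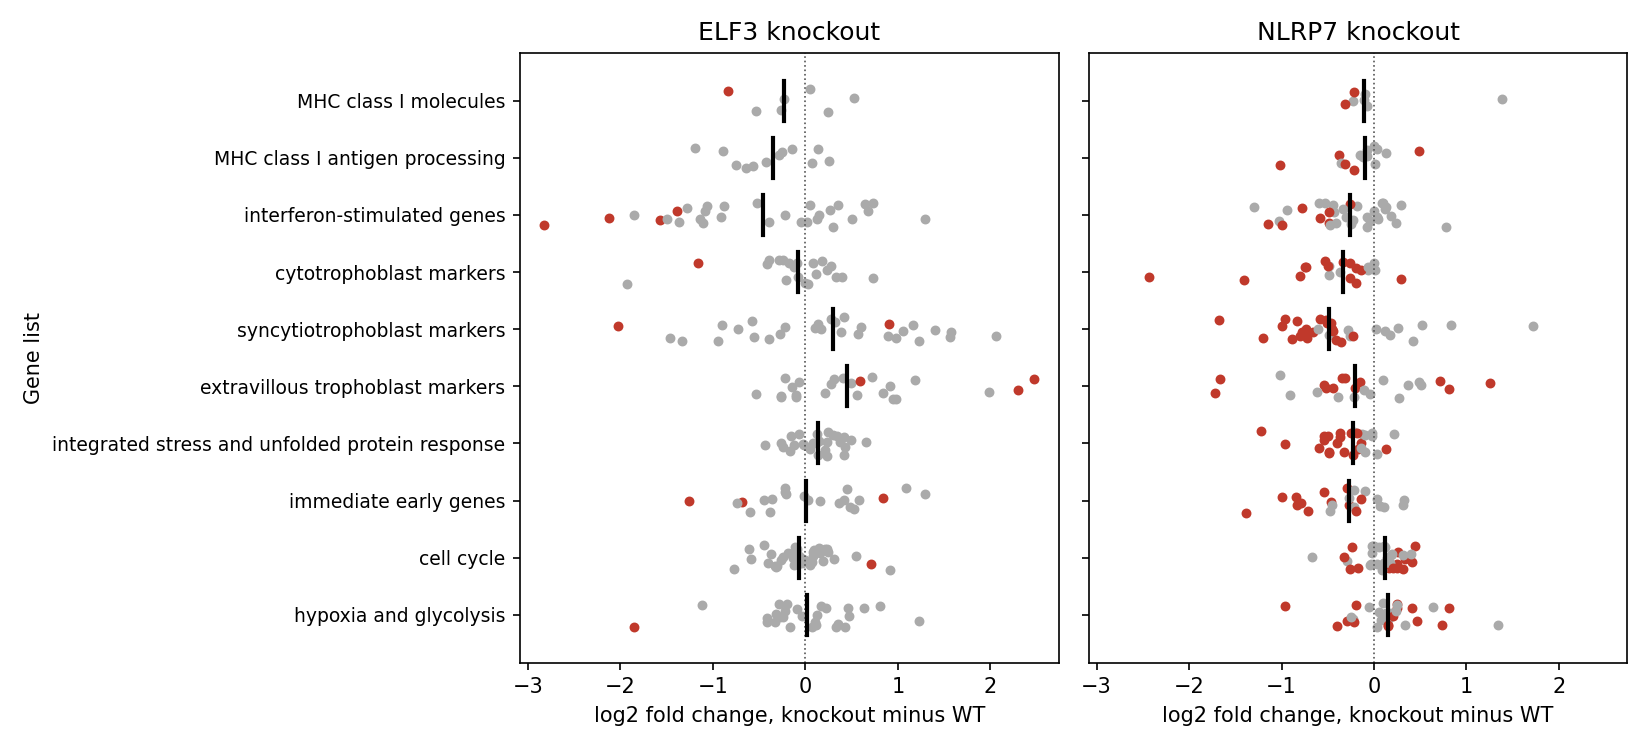
Log2 fold change, knockout minus WT, of each tested member of 10 gene lists in the ELF3 knockout (left) and the NLRP7 knockout (right). Red points passed the limma test, grey points did not, black bars mark list medians, and vertical position within a list is scatter only. Of the syncytiotrophoblast markers, 21 of 33 fell and none rose in the NLRP7 knockout, where 20.8% of all tested genes were called. In the ELF3 knockout, where 3.96% of all tested genes were called, 1 of 30 fell and 1 rose.

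Beyond the lists, HMOX1, the heme oxygenase gene, fell in the NLRP7 knockout from 1188 ± 3.65 to 79.5 ± 4.16 normalised read counts (SD, n = 3), and the cholecystokinin receptor CCKBR from 936 ± 62.7 to 13.8 ± 1.89. The melanoma antigen gene MAGEA4 (-6.34), TCEAL7 (-5.05), MAGEA9B (-3.95), DMKN (-3.75), ZNF22 (-3.58), the mucin MUC5B (-3.57), PTPRB (-3.20) and the Hedgehog effector GLI3 (-3.15) completed the 10 largest falls. MAGEA9B has a near-identical copy, so its level is uncertain. The largest rises were the GABA receptor subunit GABRB2 (4.79), NT5DC2 (4.39, from 89.4 ± 20.6 to 1862 ± 102), TCEA3 (4.27), DPYSL5 (3.94), SLC16A13 (3.46), PRRT4 (from 23.7 ± 5.71 to 225 ± 40.2), HOXB4 (3.15), C5orf63 (2.99), ZNF780B (2.98) and the clock gene PER3 (2.86). Among NLR genes, NLRX1 (2.69, SE 0.228) and NLRP11 (2.44, SE 0.538) rose and the pyroptosis effector GSDMD fell (-1.61, SE 0.334), with no shift of the list (camera adjusted p = 0.829). Of the subcortical maternal complex, TLE6 (1.34, SE 0.265) and ZBED3 (1.40, SE 0.357) rose beside the fall of NLRP7 itself (camera adjusted p = 0.902). IGF2 fell from 119589 ± 2827 to 52887 ± 2094 (SD, n = 3), and the claudin CLDN3 rose from 35.4 ± 1.19 to 190 ± 17.2, in an epithelial list with 8 of 45 up and 14 down (camera adjusted p = 0.369). The 20 tested genes nearest to IGF2 had a median log2 fold change of -0.41. Only 0.127% of all genes had such a median beyond 0.4 in either direction.

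Across all genes, limma called 2876 of 13809 changed in the NLRP7 knockout, 1254 higher and 1622 lower, and 216 rose and 201 fell at least 2-fold. Which direction held more genes depended on scaling, since upper-quartile scaling gave 1533 higher and 1378 lower and quantile normalisation 1444 and 1418. The groups separated without overlap for 38.1% of tested genes, where chance gives 10%. Leaving out single libraries gave between 2048 and 2389 changed genes, and 95 of 112 named genes past the threshold here or in the overlap stayed past it throughout.

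Both knockouts were then set side by side over the 13142 genes tested in both tables, which have no WT library in common. Changed in both were 216 genes, where independent lists would share 109.9 (Fisher's exact test, odds ratio 2.81, adjusted p = 2.64e-26). This test gives every gene the same chance of a call. Genes were not matched for level or variance, which also bear on calls, so the excess may in part reflect them. Of these 136 moved in opposite directions and 80 in the same direction. The excess was largest among genes that rose in the ELF3 knockout and fell in the NLRP7 knockout, 81 against 27.5 under independence (adjusted p = 3.85e-20), and 55 genes fell and rose, against 26.6 (adjusted p = 2.63e-07). Another 53 fell in both against 34.8 (adjusted p = 0.00219), while the 27 that rose in both were not in excess (adjusted p = 0.166). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.08 and a Spearman correlation of -0.14.

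For each combination of directions, the 5 genes with the largest smaller change of the 2 knockouts were taken. SYT5 (-8.01 in the ELF3 and 3.76 in the NLRP7 knockout), HOXB3 (-4.10 and 2.19), SLC6A11 (-4.60 and 2.19), KLK6 (-3.97 and 1.77) and TBKBP1 (-1.43 and 1.56) fell and rose. ARL14EP (4.85 and -2.61), RNF128 (-1.98 in the NLRP7 knockout), GPRC5A (1.68 and -2.14), DMKN (1.44 and -3.75) and GUCY1A2 (3.68 and -1.37) rose and fell. B4GALT6 (-3.82 and -3.45), the cancer-testis genes MAGEC2 (-4.54 and -3.08) and CTAG2 (-5.18 and -2.92), NLRP7 (-2.21 and -2.23) and MGST1 (-2.25 and -2.05) fell in both. ADCY10 (2.16 and 2.14), the germ cell factor DPPA3 (1.56 and 1.64), VIPR1 (1.78 and 1.25), MPC2 (1.33 and 1.17) and GRM4 (1.94 and 1.05) rose in both. Counting only genes changed at least 2-fold in both, 44.4% moved in opposite directions.

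**Figure D3:**
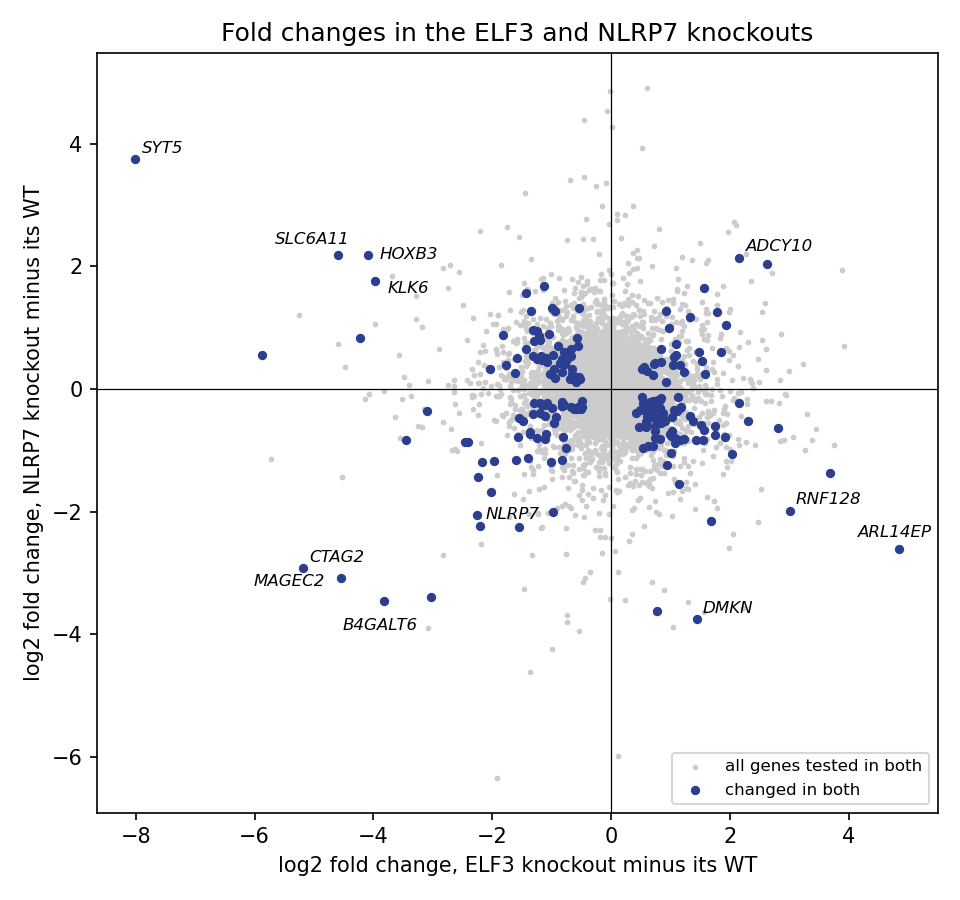
Log2 fold change in the ELF3 knockout (horizontal) against that in the NLRP7 knockout (vertical), each against the WT of its own table, for 13142 genes in grey and the 216 changed in both in blue. Blue points fill all quadrants, with 136 in the quadrants of opposite direction.

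Tested directly, the log2 fold changes of 1908 of the 13142 genes differed between the knockouts, 1033 of them higher and 875 lower in the ELF3 knockout. For HLA-C the difference was -0.62 (SE 0.195, adjusted p = 0.0531), just short of the threshold, and for HLA-G -0.22 (SE 0.266, adjusted p = 0.641). Of the lists, 6 differed, with the smallest adjusted p for integrated stress and unfolded protein response genes (median difference 0.45, camera adjusted p = 1.46e-05), syncytiotrophoblast markers (0.75, camera adjusted p = 0.000386) and extravillous markers (0.74, camera adjusted p = 0.00129), all higher in the ELF3 than in the NLRP7 change. With an estimated correlation no list differed, the adjusted p being 0.342 for the stress and extravillous lists and 0.389 for the syncytiotrophoblast list. The HLA-C difference passed without WT replicate 3 of the ELF3 table (-0.83, adjusted p = 0.000121), and the number of differing genes was 1223 without NLRP7 knockout replicate 3.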

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

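The tests of the overlap of large changes, of the genes around the targeted genes, of carried-over KCNQ1 reads and of the number 3 libraries were chosen only after the result was seen. The knockouts were compared for each gene and list that both comparisons report under a name fixed in advance, and those whose fold change differed between the knockouts stand here. ELF3 itself differed (difference of log2 fold changes -1.40, SE 0.269, limma adjusted p = 0.00509), being targeted in 1 of them. The lists that differed, with their median difference as ELF3 minus NLRP7 change, were syncytiotrophoblast markers (0.75), extravillous trophoblast markers (0.74), mesenchymal genes (0.54), integrated stress and unfolded protein response genes (0.45), cytotrophoblast markers (0.30) and p53 targets (0.25). With an estimated correlation none of the 6 differed (adjusted p = 0.389 for the syncytiotrophoblast and p53 lists and 0.342 for the other 4), and the mesenchymal, cytotrophoblast and p53 lists passed only narrowly before (camera adjusted p = 0.0476 each). Of 100 of the 200 splits of the libraries within the tables, 1, the real one, gave as many as 1908 differing genes, and the highest other gave 935. For lists, 35 of the 100 gave at least the 6 seen and the highest other gave 10, so chance cannot be excluded for the number of lists.

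Within each table only 10 splits of 6 libraries exist, too few for a share under 0.05. The real split gave 541 changed genes in the ELF3 table and the highest other 1, with 1 split reaching the real count. In the NLRP7 table these were 2876 and 1, again with 1 split. For lists, 3 splits of the ELF3 table gave at least the 6 lists of the real one and the highest other gave 10, while only 1 split of the NLRP7 libraries reached 8 lists and the highest other gave 6. The ELF3 split with 10 lists set knockout replicates 1 and 2 with WT replicate 2 against the others. List calls in that table thus also arise under groupings other than the knockout, and the reason was not tested.

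In both knockouts, genes changed at least 4-fold, 108 in the ELF3 and 117 in the NLRP7 knockout, included many near all-or-none switches. Gain or loss of a chromosome segment holding many genes is argued against for these genes only. Smaller shifts of a segment, such as that around ELF3, are not excluded. Nor is loss of a few neighbouring genes, which a median over 20 genes cannot show. Only 2.88% of those in the ELF3 knockout and 0% in the NLRP7 knockout had 20 nearest tested neighbours with a median log2 fold change beyond 0.4, against 2.81% and 0.127% of all genes. A candidate explanation is that a set of genes differs between JEG-3 cultures whichever gene was targeted. In both knockouts 12 genes were changed 4-fold, where independent lists share 0.543. The overlap exceeded that of independent lists in opposite directions (odds ratio 25.3, 95% interval 6.28 to 75.5) as in the same direction (28.9). Genes were not matched for level or variance, which may also raise such an overlap. In a test set before its result was seen, 24.2% of the genes changed 4-fold in either knockout, against 1.76% of the others, also differed at least 4-fold in RPM between the WT libraries of the tables (odds ratio 17.8, 95% interval 11.7 to 26.5), a comparison across separately made tables whose WT libraries also enter the fold changes. NLRP7 is 1 of the 12, with 337 RPM in the WT libraries of the ELF3 table and 14.6 in those of the NLRP7 table, so a direct effect of ELF3 on NLRP7 and a difference between cultures both stay open. Near NLRP7 on chromosome 19, SYT5 (from 55171200, log2 fold change -8.01) and TNNI3 (from 55151800, -5.72) fell in the ELF3 knockout. EPS8L1 (from 55072000), between them and NLRP7, rose (0.68). Whether a change of that stretch bears on NLRP7 was not tested.

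In the ELF3 table, the number 3 libraries of both groups stood apart, with the second principal component (22.4% of variance) at -38.0 for ELF3 knockout replicate 3 and -36.1 for WT replicate 3 and between 1.31 and 31.5 for the others. A culture or preparation shared by the number 3 libraries may underlie this. Their deviations from the group means correlated at 0.279 across genes, which restates the same pattern in the same libraries and does not test that cause. Number 3 against numbers 1 and 2 of the other group correlated between -0.208 and -0.102. Deviations cancel within each group, so these negative values follow from the positive one and add nothing to it. The HLA-C log2 fold change was -1.01 within numbers 1 and 2 and -0.47 between the number 3 libraries alone, which allow no test. Their mitochondrial share was 1.44 times the highest of the others, which does not decide on RNA quality, and knockout cells mixed into WT replicate 3 could neither be shown nor excluded, as it lay a median 0.233 of the way from WT to knockout (95% interval 0.0967 to 0.303 over 108 genes) where HLA-C lay at 0.719. The bound that excludes such mixing was changed after that median was seen: under the bound first written, a median below 0.25, mixing would have been excluded. The design names no biological difference between replicate numbers, so none was tested.

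KCNQ1, a potassium channel gene in an imprinted region, took 6.76% of all reads in ELF3 knockout replicate 3. It stood at 142 to 1046 RPM in the other 5 libraries of that table and at no more than 2 reads in any library of the NLRP7 table. Cells of another type in that library are argued against: in a test set before its result was seen, 3 other genes (CIITA, SRP14 and GPRASP2, named after their values were seen) reached a value of 50 and 10 times the highest of the other libraries, where foreign cells would bring many. Reads carried over from that library into the others could explain the lower levels, which reached at most 1.55% of its level, but these shares differed 7.36 times among the libraries, and no table decides it. What brought the reads into ELF3 knockout replicate 3 was not tested.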

How the results depend on the processing

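Alternatives that left out the number 3 libraries, and edgeR and DESeq2 on single genes, were chosen only after the data were seen; all others were planned. HLA-C in the NLRP7 knockout kept its direction and its call under every alternative run on that gene but the exact permutation test, which cannot pass with 3 against 3 libraries (p = 0.1 for HLA-C and the targeted gene in each table, with log2 fold changes of -0.83 and -1.31 in the ELF3 and -0.22 and -2.23 in the NLRP7 knockout). The thresholds on fold change were not run on single genes, and at -0.22 the HLA-C change is smaller than both. Its log2 fold change ran from -0.24 to -0.20 with each library left out, and NLRP7's from -2.42 to -2.03. Scaling moved HLA-C further, to -0.19 with upper-quartile scaling and -0.16 with quantile normalisation (adjusted p = 0.00619 and 0.00720). Without a variance trend its adjusted p was 0.0438. Without each library in turn the ELF3 knockout gave 110 to 503 changed genes, an HLA-C change of -1.05 to -0.70, an ELF3 change of -1.54 to -1.12 and 2 to 5 lists. The NLRP7 knockout gave 2048 to 2389 genes and 6 to 8 lists, and the knockouts differed in 1223 to 2507 genes and for HLA-C by -0.83 to -0.48.

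Without a variance trend 280 genes changed in the ELF3 and 1892 in the NLRP7 knockout, and HLA-C (-0.83, adjusted p = 0.112) and ELF3 (-1.31, adjusted p = 0.0764) lost their calls in the former. Other counts in the ELF3 knockout were 2230 with sample weights, 1295 with DESeq2, 297 at a log2 fold change of at least 1, 67 with treat against 0.5 and 1099 without the number 3 libraries. In the NLRP7 knockout the last 3 were 417, 211 and 1570. With upper-quartile scaling and quantile normalisation the NLRP7 knockout had more genes higher than lower (1533 against 1378, and 1444 against 1418), and with sample weights so did the ELF3 knockout (1120 against 1110). In the ELF3 knockout HLA-C had a smaller adjusted p with sample weights (-0.90, adjusted p = 0.00230) and without the number 3 libraries (-1.01, adjusted p = 0.00637). The edgeR test called 512 and 2833 genes. Camera called 3 lists in the ELF3 knockout with a filter at a mean of 50 and 0 in both knockouts with an estimated correlation, and fry called 16 in the NLRP7 knockout. In the ELF3 knockout fry called 4 lists, none of them among the 6 that camera called: NLR and inflammasome genes, the subcortical maternal complex, fibroblast and stromal markers and neuronal markers (fry adjusted p = 0.0488 each). The lowest fry adjusted p of the 6 was 0.0642, for interferon-stimulated genes. The HLA-C difference between the knockouts passed with that filter (-0.62, adjusted p = 0.0491), with quantile normalisation (-0.69, adjusted p = 0.0302), and without the number 3 libraries of the ELF3 table (-0.80), where 3338 genes differed. Directions turned for HLA-B in the ELF3 knockout with sample weights (-0.14), without ELF3 knockout replicate 1 (-0.07), without WT replicate 3 (-0.11) and without the number 3 libraries (-0.10). They also turned for B2M without ELF3 knockout replicate 3 (-0.12) and without the number 3 libraries (-0.0151). For the ribosomal protein list the camera direction and the median turned without WT replicate 1 (median 0.0228). Its median alone turned without ELF3 knockout replicate 3 (0.00942) and with sample weights (0.000512). With each library left out HLA-B ran from -0.11 to 0.18 and B2M from -0.12 to 0.44. None of these passed the test. Of genes changed at least 2-fold in both knockouts, 44.4% moved oppositely, against 63.0% of all shared genes. Apart from runs with fewer libraries or stricter thresholds, the cause was not tested.

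The replicate numbers did not pair the libraries throughout. Same-numbered deviations correlated at 0.140, 0.0580 and 0.279 in the ELF3 table and at -0.0628, 0.0133 and -0.0209 in the NLRP7 table. ELF3 knockout replicate 2 correlated best with WT replicate 1, but the number 3 libraries of the ELF3 table shared a shift. The main test held no block, so that shift stayed in its spread. With the numbers as a replicate block 1192 and 2626 genes changed and 7 and 8 lists passed, and HLA-C in the ELF3 knockout had an adjusted p of 0.0109. With that block the SE in the ELF3 knockout was 0.126 for HLA-C and 0.0932 for ELF3, against 0.178 and 0.229 in the main test. Among runs on other named genes, 828 stayed the same and 150 were weaker in the ELF3 knockout, against 1935 and 128 in the NLRP7 knockout.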

Other observations

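The tests of gene families were chosen only after the data were seen. Cancer-testis genes stood out among the large changes: of the MAGE, CTAG, PAGE, GAGE, XAGE and SSX genes, 4 of 22 fell and none rose at least 4-fold in the ELF3 knockout (Fisher's exact test, adjusted p = 0.000121), as did 6 of 25 in the NLRP7 knockout (adjusted p = 5.05e-07). Genes of the X chromosome, which hold most of these, made up 9 and 13 of the genes changed 4-fold (odds ratios 2.57 and 3.56, adjusted p = 0.0208 and 0.000504). The TCEAL, BEX and ARMCX family, also mostly X-linked, had 3 of 14 members changed 4-fold in the NLRP7 knockout (adjusted p = 0.000504), of which 2 fell, and 1 of 14 in the ELF3 knockout (adjusted p = 0.131). Of the HOX genes, 2 of 19 changed 4-fold in the NLRP7 knockout, both rising (adjusted p = 0.0208), and 1 of 11 in the ELF3 knockout (adjusted p = 0.119). Zinc finger genes named ZNF held 3 of 470 and 5 of 459 such genes (adjusted p = 1 and 0.664). Below that size, windows of 20 tested genes at chromosome 19 ZNF clusters had lower medians in the ELF3 knockout, but the clusters were not tested as groups. The lowest median log2 fold change was -0.96, around ZNF222 and ZNF224, which did not pass themselves (adjusted p = 0.438 and 0.723). ZNF404, which starts at 43872400 and so lies near ZNF222 (44025300), fell (adjusted p = 0.0307). Elsewhere on the chromosome ZNF790 and ZNF829 fell (adjusted p = 0.0464 and 0.0425). The window around ZNF585B had a median of -0.708 in the ELF3 knockout and of 0.438, the other way, in the NLRP7 knockout.

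The number 3 libraries of the ELF3 table had less chorionic gonadotropin transcript than numbers 1 and 2 in both groups, and the genes here were picked after their values were seen. The log2 differences were -2.13 in WT and -2.41 in the knockout for CGB3, -2.38 and -2.33 for CGB8, and -1.54 and -1.39 for CGA, whereas TAGLN was higher by 1.38 and 2.16. Over 13 mitochondrial transcripts the median differences were 0.66 and 0.81. In ELF3 knockout replicate 3, CIITA, the master regulator of MHC class II genes, stood at 1194 normalised read counts against at most 113 in the other libraries of its table. Over the 5 tested MHC class II genes, the median difference of number 3 from numbers 1 and 2 was 0.44 in the knockout and -0.46 in WT. Between the WT libraries of the tables, B2M stood at 142 and 533 RPM, HLA-G at 177 and 67.8, and HLA-C at 399 and 446, in tables normalised separately.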
